A study of Caenorhabditis elegans with 2 samples.

How the data were processed

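The data were chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for LIN-14, a nuclear protein that times larval development in the nematode Caenorhabditis elegans. Per the labels, the worms carried a transgene with the lin-14 gene fused to GFP, TY1 and FLAG tags, inserted together with a functional unc-119 copy into an unc-119 mutant. LIN-14 was precipitated with an antibody against GFP from whole L1 larvae of both sexes, aged 6 hours, which the labels describe as synchronised by starvation after bleaching. Whether they had been fed for those hours or were still starved when collected is not given in the sources used here. Chromatin was sheared by sonication. The design held 1 group with 2 biological replicates, both of the same stage and strain, and no second condition. A control experiment is named in the labels and was not analysed here as a data set of its own.

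The authors deposited 4 peak lists on the ce11 build. One list was called on each replicate, 1 on the alignments of both replicates together (the pooled list), and 1 holds the peaks that passed an irreproducible discovery rate (IDR) threshold, derived from the other 3, per the README texts deposited with the samples. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each replicate list and the pooled list was called against a control file, per the same texts. Each deposited peak has a score, the strength that the authors' peak caller gave it, which is not a read count. Scores were used to rank and describe peaks, and scales differed between lists. The deposited lists also hold the −log10 of a q-value per peak, with a ceiling of 4.29 reached by 84.3% of the IDR-thresholded peaks, so this column was not used for ranking. The summit is given by the authors as an offset from the peak start. The content of each list matched the checksum deposited with it. Read depth is unknown, since the files hold no read counts, and intervals given here cover counting of peaks or genes only.

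Gene models were taken from Ensembl release 115 for the WBcel235 assembly, and sequence from the RefSeq copy of the same assembly, whose chromosome lengths were compared with the peak coordinates. Overlapping IDR-thresholded peaks were merged into regions, each with the summit of its strongest peak, which left 11115 regions from 11507 peaks. A protein-coding gene was counted as having a LIN-14 region in its promoter window when a summit lay from 1000 bp upstream to 200 bp downstream of the 5′ end of any of its annotated transcripts. This applied to 19973 genes. A summit in such a window shows where the tagged protein was enriched and not that the gene responds to it. Annotation classes were assigned in the order promoter window, 5′ UTR, coding exon, intron, 3′ UTR, 500 bp downstream and intergenic. Distances carry a minus sign upstream of the 5′ end. Positions are counted from 1.

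Replicates were compared by the share of peaks with a summit within 100 bp in the other list, using the 11507 highest scoring peaks of each, against 100 random placements within chromosomes. Correlations of scores were taken across peaks, which are not independent replicates. Shares in annotation classes were compared with 1000 random placements within chromosomes, as a permutation test. Chromosome shares were compared with chromosome length by exact binomial tests. Gene lists were tested by two-sided Fisher's exact tests of members against all other protein-coding genes. The 18 lists and 12 families made 30 tests. Sequences within 50 bp of the summits were compared with windows centred 300 bp to either side by exact sign tests, for 11 sequences chosen in advance and for all 2080 6-mers merged with their reverse complements. The larger of the adjusted p-values for the left and right windows is given. Adjustment was by the Benjamini-Hochberg method within each family of tests, with a threshold of 0.05. Confidence intervals are 95% exact binomial (Clopper-Pearson) intervals, which treat genes and regions as independent although neighbouring genes can share a region. Scores of promoter regions and other regions were compared by a permutation test with 100000 resamples.

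Groups, tests, gene lists, sequences and most alternatives were fixed before the data were examined. The genes named are the 20 with the highest promoter scores, all heterochronic genes with a promoter region, and lin-14, lin-4, ins-33, lin-28 and unc-119 in any case. Of every other list up to 4 members with the highest scores are eligible, and of regions outside promoter windows the strongest 5. Genes named beyond that rule are marked as such. Alternatives covered the promoter window, the rule that assigns regions to genes, the background of the gene list tests, a stricter score threshold, the matching distance, merging, and the top peaks of a single replicate in place of the IDR-thresholded list. The chromosome comparison without the transgene loci, its split by promoter, the same split for YGGAR, the tissue comparisons and their settings, and the chemoreceptor count without other sr genes were added after seeing the data.

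The tests were checked on simulated data. With 50 simulated lists of 40 genes bound at 2 times the rate of the other genes among 19973, 68.0% were called, and 0 of the lists bound at the common rate were called. A simulated X chromosome with 1.2 times the autosomal density among 11000 regions was called in 100% of 50 draws. Simulated regions and list members were drawn independently, so these checks do not cover clustering of regions or of family members along chromosomes. The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.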

Results

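LIN-14 is a nuclear protein that sets the fates of the first larval stage, and its abundance falls after that stage when the lin-4 microRNA represses it. The labels describe a genome-wide map of tagged LIN-14 in L1 larvae of 6 hours, without stating whether these had been fed or were still starved, with 2 biological replicates of 1 group. The question that such a map answers is which genes and sequences the protein occupied at this stage, and how closely the replicates agree. Replicate 1 had 25357 peaks, replicate 2 had 27170, and the list called on both together had 24683. The IDR-thresholded list, used below unless another is named, held 11507 peaks with a median width of 353 bp, which covered 3.67% of the genome. All of its peaks were in the pooled list, of which they made up 46.6%. Scores are the authors' and ran from 147.5 to 13287.5 with a median of 358.7. Where a gene's score is given with both replicates, those values come from the replicate lists and are on a lower scale than the first.

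Most of the highest scoring LIN-14 peaks were shared by the replicates. Among the 11507 highest scoring peaks of replicate 1, 84.6% had a summit within 100 bp in the equally long list of replicate 2 (95% interval 83.9 to 85.2%), against 2.39% for randomly placed peaks. The reverse comparison also gave 84.6%. Without a limit on score, 70.2% of replicate 1 peaks and 65.5% of replicate 2 peaks had a match. The IDR-thresholded list amounted to a score cut of the pooled list, with its lowest score at 147.478 and the highest score left out at 147.472. Pooled scores come from the reads of both replicates. The match of this list in both replicate lists (96.6%) and the correlations over it are therefore no independent measure of agreement. Across its 11120 peaks matched in both, Spearman's rho of the scores was 0.92 and Pearson's r of the log2 scores was 0.93. These are correlations across peaks, not across samples. Scores were higher in replicate 1 by a median of 0.35 on the log2 scale (SD of the differences 0.41), and after that shift 328 peaks differed by over 2-fold. The scale of the scores is not given in the sources used here, so that shift cannot be read as a difference in occupancy. The rule for a match set the overlap between 65.5% for all peaks and 88.9% for any overlap of the top peaks.

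**Figure D1:**
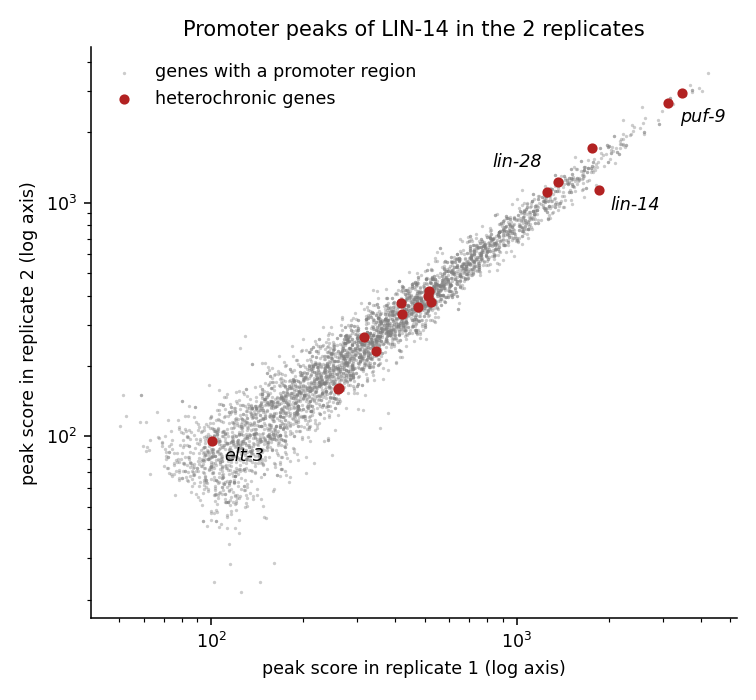
Peak scores in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes, for the strongest promoter region of each protein-coding gene that was matched in both lists. Red points are heterochronic genes, among which puf-9 had 3128 and 2672 and elt-3 had 101 and 95.1.

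The lin-14 gene itself was among the most densely occupied loci. From 5 kb upstream to 1 kb downstream of lin-14 (chromosome X, 11465560 to 11485871, plus strand) there were 18 regions. The strongest, at 11472919 to 11473875 with its summit at 11473493 in an intron, had a score of 4551 (replicates 2561 and 2003) and rank 37 of all regions. A region at 11464319 to 11465658 covered the 5′ end, with its summit 205 bp upstream and a score of 2970 (replicates 1858 and 1127). Within 20 kb of the gene there were 0.36 regions per kb, against a median of 0.14 around other X-linked genes, which placed lin-14 at percentile 97.5. The strain carries additional lin-14 sequence in its transgene, and peaks from the native and the inserted copies cannot be separated in these lists. The other gene in the transgene, unc-119, had no promoter region and stood at percentile 21.6, with its strongest region in an intron (score 1027).

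**Figure D2:**
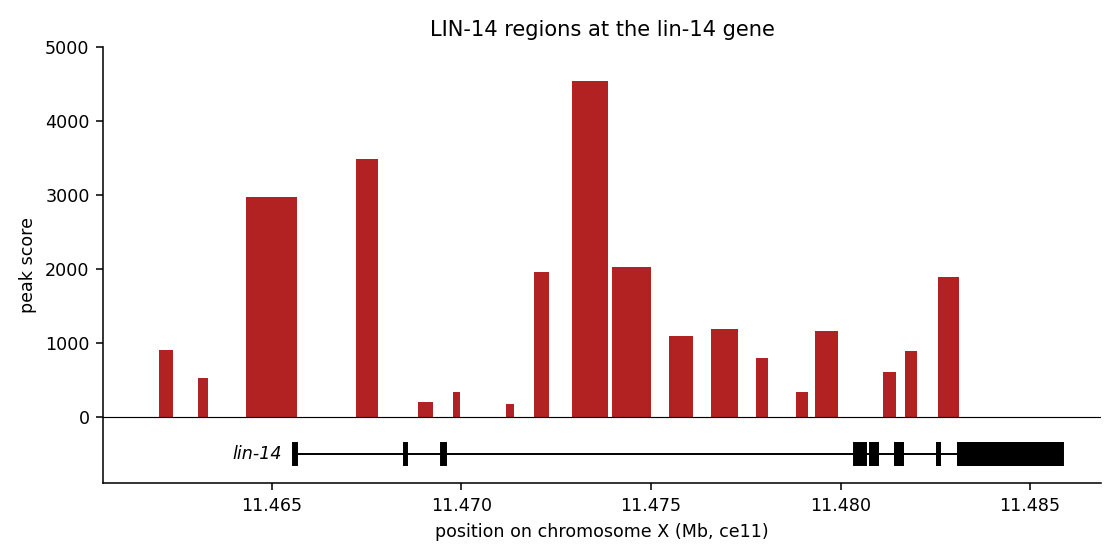
Score (vertical) and extent (horizontal, position on chromosome X in Mb, ce11) of the 18 LIN-14 regions from 5 kb upstream to 1 kb downstream of lin-14, with the annotated exons as black boxes below. The highest bar, 4551, lies in the long intron.

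Genes of the heterochronic pathway, which orders developmental events between larval stages, had LIN-14 regions in their promoters more often than other genes. This held for 17 of 25 protein-coding members (68%, interval 46.5 to 85.1%), against 22.9% of the other genes (Fisher's exact test, adjusted p = 1.0e-05), and the call held in all 11 alternatives. The highest scores belonged to nhl-2, a cofactor of microRNA silencing (6411, replicates 3478 and 2955), and puf-9, a Pumilio-family RNA-binding protein (5762, replicates 3128 and 2672). The region at nhl-2 lay nearer to the divergent gene tag-340 (592 against 831 bp upstream) and cannot be assigned to either gene. Next came ain-1, a GW182-family partner of Argonaute proteins, with 3454, then lin-14 and lin-28, the RNA-binding protein that acts beside lin-14 in early larvae, with 2575 (replicates 1366 and 1220). The lin-66 promoter had 2364. The Argonaute genes alg-1 (788) and alg-2 (936), the nuclear receptor genes nhr-25 (902), nhr-85 (834) and nhr-23 (576), and kin-20 (878), lin-46 (755), dre-1 (576), sea-2 (421), mab-10 (411) and elt-3 (199) completed the group. Several of these summits lay inside the gene, in the window of a shorter annotated transcript. Examples are sea-2 (summit 3961452, gene start 3950377), elt-3 (13939567, gene start 13934874) and dre-1 (6538493, minus strand, gene end 6546500). The lin-28 summit lay 859 bp inside the gene. Peaks at some other members lay outside the promoter window. The RING-finger regulator lin-41 had a region of score 4545 and rank 38 at 1456 bp upstream, hbl-1 had one at 1024 bp upstream (1058) and a stronger one farther upstream (1489), and the steroid receptor gene daf-12 had one of 2812 in an intron, 1740 bp inside the gene. These 3 genes are named beyond the rule and were chosen after their values were seen. Of the other protein-coding members without a promoter region, lin-42 (1262), ain-2 (1082) and blmp-1 (1074) had regions of similar score to hbl-1 inside or near the gene. They were also chosen in that way. The rest were lin-29, with 1 region of score 222, and lep-2, with none from 5 kb upstream to 1 kb downstream.

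The genes lin-4 and ins-33 both have known links to lin-14, and lin-4 had 1 region of low score while ins-33 had none. At lin-4 (chromosome II, 5902254 to 5902347), the microRNA that represses lin-14, 1 region lay 422 bp upstream with a score of 206 (replicates 136 and 73.9), rank 8925. That is within the distance of the promoter windows, which were set for protein-coding genes only, and the score is above that of elt-3 (199). No region was found from 5 kb upstream to 1 kb downstream of ins-33 (chromosome I, 13637845 to 13639311), an insulin-like gene described as repressed by LIN-14. Among 39 insulin-like peptide genes only ins-39 had a promoter region (score 1533), which is 2.56% of them (interval 0.065 to 13.5%; Fisher's exact test, adjusted p = 0.0032). With the stronger 50% of the regions that call was lost (exact test, adjusted p = 0.064). Components of insulin signalling downstream of these ligands had regions in 8 of 17 cases (47.1%), among them the FOXO gene daf-16 (1992), the kinase gene akt-2 (2071) and the 14-3-3 genes par-5 (1462) and ftt-2 (1450, matched in replicate 1 only). That share differed from the share of the ligands (Fisher's exact test, adjusted p = 0.00039 over 6 list comparisons chosen after seeing the shares), but the list by itself missed the threshold against other genes (Fisher's exact test, adjusted p = 0.073). It passed in 5 of 11 alternatives.

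Tissue lists differed in how many members had a LIN-14 promoter region. Body wall muscle genes had the highest share among the tissues, with 32 of 45 (71.1%, interval 55.7 to 83.6%; Fisher's exact test, adjusted p = 5.6e-11), and this call held in all 11 alternatives. It included unc-60, which encodes ADF/cofilin (2837, replicates 1569 and 1272), unc-112, a kindlin of muscle attachment sites (2781), unc-115, an actin-binding protein (2363), and the actin gene act-2 (1620). Neuron terminal markers had 18 of 43 (41.9%; Fisher's exact test, adjusted p = 0.019), with unc-76 (2937), the pan-neuronal gene rgef-1 (1734), the synaptic vesicle gene rab-3 (1494) and the neuropeptide-processing gene egl-21 (1494). That call was lost against genes with named symbols only (adjusted p = 0.10, exact test) and against genes matched on upstream distance (adjusted p = 0.054, permutation test). Intestine markers had 7 of 41 (17.1%) and pharynx markers 9 of 31 (29.0%), and neither passed the test against other genes. Both shares depended on the setting. Intestine was at 41.5% with the window from 2000 bp upstream to 500 bp downstream and at 39% with the nearest gene, above other genes (29.6 and 28.0%) but without passing, and in the stronger 50% of the regions intestine was at 4.88% and pharynx at 6.45%. The muscle share exceeded that of intestine (Fisher's exact test, adjusted p = 2.7e-06), of pharynx (exact test, adjusted p = 0.00083) and of neuron markers (exact test, adjusted p = 0.014), in the same 6 comparisons. In 4 other settings the excess over intestine and pharynx held, while that over neuron markers was lost in the stronger 50% (exact test, adjusted p = 0.091) and with the nearest gene (exact test, adjusted p = 0.071). Examples in the lower 2 lists were erm-1 (828), fat-6 (418) and pept-1 (225) in intestine and peb-1 (1114), pqn-71 (679) and ceh-22 (285) in pharynx. The samples were whole animals, so the lists show which genes were occupied, not in which tissue.

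Promoters of ribosomal protein genes had the highest share of the 30 lists with the main window, though not with wider or nearest-gene assignment. LIN-14 regions lay in the windows of 61 of 79 genes for cytosolic ribosomal proteins (77.2%, interval 66.4 to 85.9%; Fisher's exact test, adjusted p = 3.3e-23). The scores were also high, 7747 at rpl-3, 6440 at rpl-20, 5935 at rpl-15 and 4745 at rpl-35. With the nearest gene the share was 48.1%, below those of muscle (86.7%) and heterochronic genes (84%), and with the window from 2000 bp upstream to 500 bp downstream heterochronic genes (92%) and muscle genes (84.4%) were above ribosomal genes (83.5%). When regions in 2 or more windows were left out the ribosomal share was 24% and the call was lost (adjusted p = 0.11, exact test). Cell cycle genes had 17 of 40 (42.5%; Fisher's exact test, adjusted p = 0.019), including pcn-1, which encodes PCNA (2430), the retinoblastoma-family gene lin-35 (2244), lin-23 (2016) and cdc-14 (1885). That call was lost in 4 of 11 alternatives.

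Several large families had few LIN-14 promoter regions. Chemoreceptor genes had a promoter region in 33 of 1371 cases (2.41%, interval 1.66 to 3.36%; Fisher's exact test, adjusted p = 1.8e-110). One of them, srgp-1, encodes a GTPase-activating protein and was taken in by its name, and without it and other such genes the share was 29 of 1354 (2.14%). The strongest member was srh-2 (4510), with srh-89 at 1512 and sri-5 at 1327. F-box genes had 17 of 322 (5.28%; Fisher's exact test, adjusted p = 2.6e-17), such as fbxa-90 (1692) and fbxb-85 (1643), and C-type lectins had 7 of 240 (2.92%; Fisher's exact test, adjusted p = 1.3e-17), led by clec-140 (1994). No region lay at any of 31 major sperm protein genes (upper bound of the interval 11%; Fisher's exact test, adjusted p = 0.0018), a call that was lost when regions were given to the nearest gene (9.68%, exact test, adjusted p = 0.051). Germline markers had 6 of 64 (9.38%; Fisher's exact test, adjusted p = 0.019), among them ifet-1 (3049), rad-51 (2330) and nos-3 (750), and hedgehog-related genes had 6 of 58 (10.3%; Fisher's exact test, adjusted p = 0.047), including wrt-3 (613) and grl-11 (572). Calls for these last lists were lost in 3 and 8 of 11 alternatives. In sequence families whose copies are nearly identical, the treatment of reads that map to several copies is not given in the sources used here, and shares can be too low for that reason.

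The other 18 lists did not pass the test. Seam cell and epidermal fate genes had 13 of 32 (40.6%; Fisher's exact test, adjusted p = 0.069), with lit-1 (1145), peb-1 (1114) and apr-1 (987), and passed in 5 of 11 alternatives. Hox genes and cofactors had 6 of 11 (54.5%; Fisher's exact test, adjusted p = 0.053), with ceh-20 (1311), lin-39 (911), unc-62 (649) and ceh-13 (430). This list passed in 3 alternatives, but with a window from 500 bp upstream to 100 bp downstream its share was 18.2%, against 17.6% of other genes. Molting genes had 14 of 44, among them myrf-2 (3165), myrf-1 (2280) and pan-1 (805), and regulators of L1 arrest and dauer had 8 of 24, among them din-1 (2810), aak-2 (1435) and daf-3 (1253). Neuronal fate and remodelling genes had 14 of 45, with unc-37 (1684), unc-42 (1063) and unc-40 (984), and neuropeptide genes had 19 of 82, with nlp-31 (603). Cuticle genes stayed near or below the genome share, with 1 of 20 collagens of known mutant phenotype (dpy-10, 298) and 32 of 156 col- genes, including col-38 (1409) and col-10 (1256). Nuclear hormone receptor genes had 63 of 269, with nhr-48 (3968), nhr-58 (3093) and nhr-1 (2847). Counts were 14 of 63 for ceh- homeobox genes (ceh-38, 2698), 4 of 25 for hlh- genes (hlh-11, 3795, and hlh-30, 1276), 22 of 72 for his- genes (his-37, 7068), 18 of 74 for cytochrome P450 genes (cyp-13A2, 1530) and 17 of 67 for UDP-glucuronosyltransferases (ugt-18, 777). The molting, L1 arrest, neuronal fate and his- lists each passed in 1 alternative. None of 6 vitellogenin genes had a region, with an upper bound of 45.9%.

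**Figure D3:**
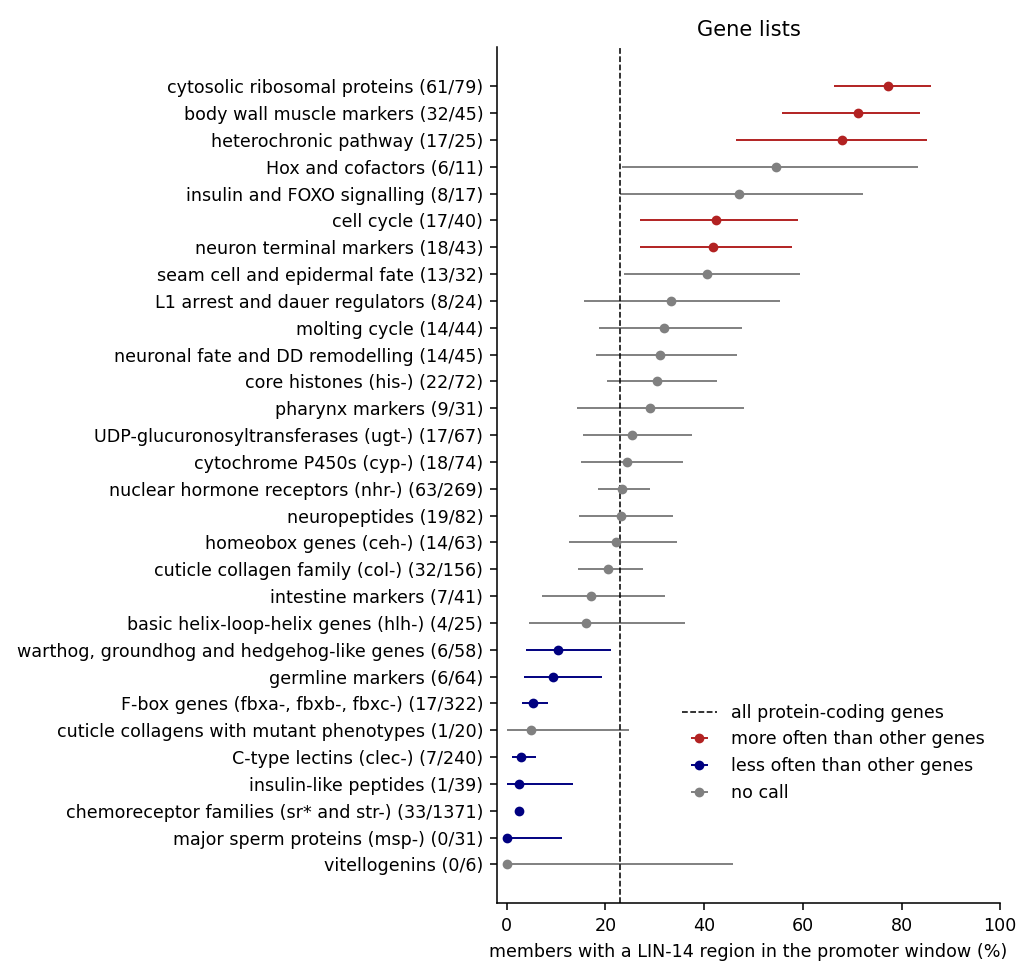
Share of each gene list with a LIN-14 region in the promoter window (horizontal, percent), with 95% exact binomial intervals as bars and counts in parentheses. The dashed line is the share of all protein-coding genes, 23%, and heterochronic, muscle and ribosomal protein genes lie at 68 to 77.2%.

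Over the genome, 4586 of 19973 protein-coding genes (23%) had a region in the promoter window, and 579 had more than 1. The top 20 by score included rpl-3 (chromosome III, 3867854 to 3869587, summit 272 bp upstream), the histone gene his-37 (chromosome V, 9547105 to 9547607, 97 bp upstream), cbp-1, which encodes the p300/CBP acetyltransferase (7016, 840 bp upstream), and epn-1, which encodes epsin (6837, 471 bp upstream). They also held the divergent pair K01G5.10 and tasp-1 (6735), F48G7.4 (6708), Y17G9B.5 with rpl-20, tag-340 with nhl-2, K11H12.8 with rpl-15, and the AAA ATPase gene cdc-48.1 (5859). The rest were puf-9, T28B11.1 (5426), tos-1 (5156), serp-1.1 (5136) and the pair F54C9.14 and iff-2 (5060), the latter encoding translation factor eIF5A. In divergent pairs a single region lies in both windows and cannot be assigned to either gene. The region with the highest score of all, 13287.5 (replicates 7583 and 5757), lay outside promoter windows of protein-coding genes at 1151248 to 1152249 on chromosome V, in intergenic sequence within 300 bp of linc-128 and 4740 bp from the 5′ end of cmd-1, the nearest protein-coding gene. The next strongest of this kind lay in introns, of pqn-41 (chromosome III, 1920932 to 1921815, score 8057, and 1924926 to 1925645, score 6175), of Y111B2A.12 (chromosome III, 12612370 to 12612999, 7077) and of zfp-1 (chromosome III, 8795576 to 8796198, 5785).

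LIN-14 regions lay more often than random placements in promoter windows and intergenic sequence, and less often in coding exons, 3′ UTRs and introns. Summits fell in promoter windows in 4498 of 11115 regions (40.5%, interval 39.6 to 41.4%), against 25.7% for random placements, a ratio of 1.58 (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Intergenic sequence held 30.6% against 22.1% at random and introns 23.1% against 27.3%. Coding exons held 1.12% against 18.7%, and 3′ UTRs 0.75% against 2.35% (two-sided permutation p = 0.002 for each of these 4 classes, the smallest possible). The 5′ UTRs (0.35%) and the 500 bp downstream of genes (3.6%) did not differ from random placement. Promoter regions had higher scores than other regions, with medians of 444.8 and 324.5, a ratio of 1.37 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give).

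The X chromosome had more LIN-14 regions than its length predicts. It held 2855 regions, 161 per Mb, which is 25.7% of all regions on 17.7% of the genome, a ratio of 1.45 (exact binomial test, adjusted p = 9.4e-98). Chromosomes IV and V had the lowest ratios, 0.77 and 0.79 (exact binomial tests, adjusted p = 4.5e-31 and 4.2e-32). Chromosome I was at 0.93, II at 1.06 and III at 1.04, and the last did not pass (exact binomial test, adjusted p = 0.073). The small departures of I and II were lost in the stronger 50% of the regions and without replicate 1, and III passed in the stronger 50% (1.14) and without replicate 2 (1.05). The share of genes with a promoter region was highest on X, at 33.9% (interval 32.1 to 35.7%), and lowest on chromosome V, at 16.8%. Not every chromosome ranked alike by genes and by regions. Chromosome III had a higher share of genes than II (27.3 against 23.5%) but fewer regions per Mb (116 against 118). On the autosomes, 50.4% of the regions lay in the central part of each chromosome that makes up 33.3% of its length (exact binomial p = 6.8e-224). The arms of these chromosomes hold many of the chemoreceptor and F-box genes. Whether that accounts for the share in the central part was not tested.

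**Figure D4:**
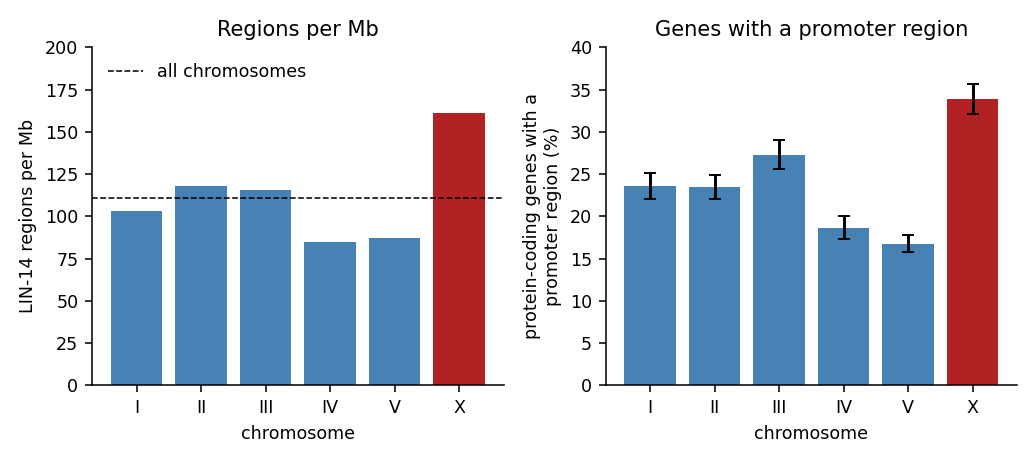
LIN-14 regions per Mb of each chromosome (left) and the share of its protein-coding genes with a promoter region (right, percent, with 95% exact binomial intervals). Chromosome X stands at 161 regions per Mb and 33.9% of genes.

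Sequence under the summits was rich in GA repeats and CG-containing words, while the 5-base site described for LIN-14 was found in only slightly more summit windows than flanking windows. YGGAR (Y is C or T, R is A or G), the published LIN-14 site, lay within 50 bp of 56.8% of the summits and in 54.3% of the flanking windows, a log2 ratio of 0.06 (exact sign test, adjusted p = 0.0003). In promoter regions alone, a split added after seeing the data, that call was lost (log2 ratio 0.03, exact sign test, adjusted p = 0.30), and in the other regions it held (0.09, exact sign test, adjusted p = 0.00016). Within 25 bp of the summits YGGAR had a log2 ratio of 0.12 (34.7% against 31.9%, exact sign test, adjusted p = 0.00044), and within 100 bp 0.041. Most windows hold its GGA core, of which there were 278 sites per 100 summits against 219 per 100 flanks, 1.27 times as many. The repeat GAGAGA occurred at 26.8% of summits against 5.46% of flanks, a log2 ratio of 2.29. The E-box CACGTG occurred at 4.82% against 1.41% (log2 ratio 1.77, exact sign test, adjusted p = 9.4e-47), and GGGTGG at 4.39% against 1.74% (1.33). Smaller ratios were found for the nuclear receptor site AGGTCA (0.57), the DAF-16 site GTAAACA (0.56, a call lost in the stronger 50% of the regions) and TTTCWYTT, a pattern like that of BLMP-1 (0.41). GATA sites had a log2 ratio of 0.10 and lost the call with wider or narrower windows, with the stronger 50% of the regions and without replicate 1. AP-1 sites did not pass (log2 ratio 0.25; exact sign test, adjusted p = 0.45), although they did within 100 bp (0.29; exact sign test, adjusted p = 0.026), and stood at -0.052 in the stronger 50% of the regions. Runs of 8 T were less frequent at summits (6.42% against 12.6%). Among all 2080 6-mers, 925 were more frequent at summits and 605 less frequent. The highest ratio in this setting was that of ACGCAG (GCGCGC without replicate 1 and with windows of 100 bp either side), at 10.9% of summits against 1.70% of flanks (log2 ratio 2.67, exact sign test, adjusted p = 2.1e-186), followed by GCGCGC (2.57), GACGCA (2.54), CGTCTC (2.51) and AGACGC (2.45).

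**Figure D5:**
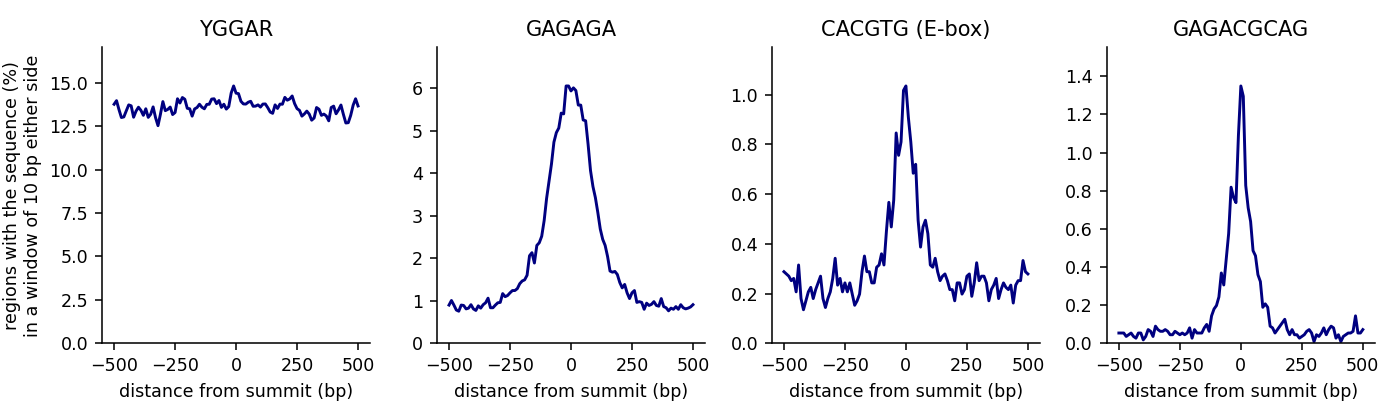
Share of the 11115 regions (vertical, percent) with each sequence in a window of 10 bp either side of a point at the given distance from the summit (horizontal, bp). The windows of GAGAGA, CACGTG and the 9-base word GAGACGCAG, which was added after the 6-mers were seen, peak at the summit. The trace of YGGAR rises only slightly there, to 14.8% at -10 bp, against 13.9% at -300 bp and 13.2% at 300 bp.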

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

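The test of peaks below the threshold was chosen after the lists had been read. Peaks that were called on both replicates together but are absent from the IDR-thresholded list stood out, because they are a signal that no comparison above used. There were 13176 such peaks, and 48.7% of them (6417, interval 47.8 to 49.6%) had a summit within 100 bp in both replicate lists. Randomly placed peaks gave a mean of 3.59% and at most 3.98% in 100 placements. Their median score was 63.9 and their highest 147.472, and none reached the lowest score of the IDR-thresholded list, 147.478. Of these weaker peaks, 30.6% lay on X, against 25.9% of the IDR-thresholded peaks. Since the pooled list was made from the same reads as the replicate lists, the match is not independent evidence, and no explanation was tested.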

How the results depend on the processing

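The X-chromosome alternatives by locus and class, the other settings of the tissue comparisons, the prefix scan against named genes only and the chemoreceptor count without other sr genes were added after seeing the data. No paired analysis was possible because the design has 1 group. The promoter excess, the higher scores of promoter regions, the X excess and the excess of GAGAGA and CACGTG kept their direction and call in every alternative run. The X ratio was 1.28 in the stronger 50%, 1.42 to 1.43 with a single replicate, 1.45 without the transgene loci, 1.28 for promoter regions and 1.57 for other regions. Where a value below moved, the cause was not tested, except that a wider window, a nearest-gene rule or fewer regions changes the counts by construction. Matching of replicate 1 peaks in replicate 2 was 76.4% at 50 bp, 87.1% at 250 bp, 87.3% with 1 bp of overlap, 73.3% with reciprocal overlap of 50%, 70.2% for all peaks and 88.7% for the top 50%; the reverse gave 76.4, 88.7, 88.9, 74.1, 65.5 and 88.7%. For the top 50% of the peaks rho was 0.93 and r 0.96, and with 1 bp of overlap 0.88 and 0.88. Genes with a promoter region numbered 3046 in the stronger 50% of the regions, and 4748 and 4687 with the top peaks of replicate 2 and replicate 1 alone. Lists with more regions than other genes numbered 5, and 9 with the window from 2000 bp upstream to 500 bp downstream, 8 with the nearest gene and 3 against named genes only. Lists with fewer numbered 7, and 4 in the stronger 50% and 4 with the nearest gene. Single lists that changed are given beside their values. Reversals without a call occurred in several lists. In the stronger 50%, neuropeptide genes were at 6.1% against 15.3% of other genes (Fisher's exact test, adjusted p = 0.059). Neuronal fate genes were at 13.3% against 15.3% in that setting. With the nearest gene, his- genes were at 20.8% against 28.1%. Of the annotation classes, the 500 bp downstream of genes reversed (3.17% in the stronger 50% and 3.47% without replicate 2, against 3.6% in all regions). With a single replicate the range was 3.47 to 3.51%, and 3.51% was no reversal. Chromosome I went from 0.93 to 1.03 in the stronger 50%, chromosome II from 1.06 to 1.00 (0.998) outside promoters, and GATA sites to -0.040 in the stronger 50%. The log2 ratio of YGGAR was 0.032 in promoter regions alone, where its call was lost, and 0.087 in the others, a split added after seeing the data. The density around lin-14 fell to percentile 86.6 with a window of 50 kb. Depth is unknown, so absence of a region at a gene means only that none passed the authors' threshold.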

Other observations

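The comparisons in this part were chosen after seeing the data, except that the tests of the X excess in the highest-scoring 10% and without GAGAGA, of YGGAR without GA words, and of the lin-14 gene body and flanks had their outcomes fixed before they were run. Genes named here fall outside the rule for named genes. A scan of all 117 symbol prefixes with at least 15 protein-coding genes found 14 with more promoter regions than other genes and 33 with fewer (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted). Beside rpl- (37 of 47) and rps- (26 of 31), the former included the unc- genes, defined by uncoordinated movement (60 of 94, 63.8%; exact adjusted p = 1.1e-15), the lin- genes, defined by cell lineage defects (27 of 47, 57.4%; exact adjusted p = 2.8e-06), dnj- (18 of 29), vps- (17 of 31), sec- (12 of 19), eif- (13 of 25) and tag- (25 of 57). The other 5 were mig- (9 of 16), tbc- (9 of 17), hsp- (11 of 22), vha- (10 of 20) and cyn- (8 of 16), and these 5 were lost against genes with named symbols only (exact adjusted p = 0.053 to 0.12), of which 27.5% had a promoter region. Prefixes that did not pass included rab- (9 of 20), npp- (11 of 26), cox- (7 of 15), ubc- (8 of 21), mdt- (7 of 20), taf- (6 of 17), cdc- (5 of 16), mrpl- (14 of 41) and mrps- (8 of 29). Each of these shares was above the 23% of other genes, from 27.6% for mrps- to 46.7% for cox-. Among named genes only, mrps- had no excess (27.6% against 27.5%). Other prefixes that did not pass lay below other genes, such as skr- (3 of 20), wdr- (3 of 15) and gly- (4 of 20). An excess can be missed in families this small. Whether the calls extend to cell machinery in general stays open, since that was not tested as a list. Among the 33 prefixes with fewer promoter regions were srx- (0 of 101), srw- (1 of 109), the cuticlin-like cutl- genes (0 of 29) and the ligand-gated channel genes lgc- (5 of 56, 8.93%, Fisher's exact test, adjusted p = 0.028). Named genes more often had a promoter region than other genes, which is a limit of all prefixes with an excess in the main scan. Against named genes only, 9 prefixes had more and 34 fewer, the added one being grl- (2 of 31; exact adjusted p = 0.021).

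Genes without a protein product were not part of the gene list tests. With the same window, which for short genes also covers the gene and sequence beyond it, a summit lay within the window of 149 of 346 snoRNA genes (43.1%, against 12.2% for regions placed at random on the same chromosomes), 247 of 612 tRNA genes (40.4% against 14.1%), 57 of 194 lincRNA genes (29.4% against 12.7%), 68 of 261 microRNA genes (26.1% against 13.2%), 23.3% of snRNA genes (against 11%) and 2685 of 7764 other ncRNA genes (34.6% against 13.3%). piRNA genes had 700 of 15363 (4.56% against 9.84%) and pseudogenes 76 of 2128 (3.57% against 11.4%), below random (two-sided permutation, p = 0.002 before adjustment, the smallest that 1000 placements can give, and 0.0025 after it, for each of these 8 of 10 classes). Antisense RNA genes (15 of 100) and rRNA genes (0 of 20) did not differ. Many of these genes lie inside or beside protein-coding genes, and that was not adjusted for. Of the 25 heterochronic genes, 24 had a region somewhere from 5 kb upstream to 1 kb downstream, lep-2 being the exception, against 45.1% of all protein-coding genes, which were not matched on length. The genes with the most regions in their bodies were kin-1, which encodes the catalytic subunit of protein kinase A (17 in 38.5 kb), lin-14 (15 in 20.3 kb), lim-9 and mpz-1 (14 each), and daf-5, nhr-27 and unc-73 (13 each). Regions at ribosomal protein genes had a median score of 1137, against 438.5 for other promoter regions (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The 10% of regions with the highest scores covered 26 ribosomal protein genes, and 56.3% of it lay in promoter windows against 31.5% of the lowest 10%.

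The excess of regions on X was set against 4 technical explanations, each by a ratio that would reach 1 if it were the whole cause. The first 3 are ratios to the share of length. Leaving out the transgene loci gave 1.45 (interval 1.40 to 1.49), the highest-scoring 10% 1.35 (1.21 to 1.5), the next 10% 1.14 (1.005 to 1.28), and regions with no GAGAGA within 100 bp 1.66 (1.59 to 1.72). Intergenic regions per Mb of intergenic sequence were 193 on X and 146 on the autosomes, a ratio of X to autosomes of 1.32 (1.23 to 1.43). That value and the highest-scoring 10% argue against more non-coding sequence and calls near the detection limit as the whole cause. X kept 2833 of its 2855 regions without the transgene loci, so regions there were too few to be the whole cause. GAGAGA was 0.92 times as dense on X as on the autosomes and lay at 20.4% of X-linked against 29% of autosomal summits. Leaving those regions out was thus bound to raise the ratio, but the lower density argues against GAGA repeats as the whole cause. The ratio to the share of length was higher among weak regions, 1.73 in the lowest 10%, and calling may therefore add to it. How the control covers X stays open, since it was not analysed here, and the design offers no biological contrast, so that none was tested.

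YGGAR had only a small excess at the summits. Over all regions it stood at percentile 6.78 of the 59 other orders of its 5 letters, and a bound set beforehand on that percentile was dropped, because base composition would leave the other orders without an excess too. In the 5540 regions with neither GAGAGA nor GAGACG within 100 bp, the median log2 ratio of the other orders was 0.35, above that of YGGAR by 0.30 (95% bootstrap interval 0.26 to 0.34). Those orders can overlap other enriched words. They are also no matched reference, because over all regions YGGAR had the highest flank share of the orders (54.3%), which limits its ratio. The order nearest in flank share, YGGRA (53.1%), had a log2 ratio of -0.0013 over all regions, so the comparison cannot decide on base composition. In the same 5540 regions the log2 ratio of YGGAR was 0.042 (95% bootstrap interval -0.0014 to 0.085). That argues against crowding by exact copies of GAGAGA or GAGACG. The other orders kept an excess there (median 0.35), so other GA-rich sequence can remain in these regions. Crowding by GA-rich promoters in general therefore stays open. Also open and untested is whether many strong sites, ribosomal protein genes among them, are promoters at which many factors are recovered, for which peak lists of other proteins or of an untagged strain would be needed.

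Several of the top 6-mers overlap in the word GAGACGCAG, found at 6.32% of summits against 0.36% of flanks. It lay at 2.35% of X-linked summits against 0.16% of their flanks (log2 ratio 3.90) and at 7.70% of autosomal summits against 0.42% (log2 ratio 4.18). The word was 0.37 times as dense on X as on the autosomes.

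The dense occupancy of lin-14 was not matched by its length. Its 0.74 regions per kb of gene body lay at percentile 99.3 of 150 other X-linked genes of 10 kb or more, whose median was 0.16. The 10 kb on either side held 3 regions, 0.15 per kb, at percentile 44.7 of such flanks, and so the density was that of the gene body. Binding of LIN-14 to its own gene and extra copies of the gene in the transgene cannot be told apart, because the ends of the inserted piece are not given in the sources used here and a piece limited to the gene could give the same picture.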
